A study of Mus musculus with 6 samples.

How the data were processed

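The series holds 6 single-channel Agilent mouse expression arrays, 1 for each combination of genotype label (wild type or Satb1-null) and sorted fetal liver population (HSC, LMPP or CLP). Groups were taken from the sample titles and characteristics. Per the labels' protocols, RNA was prepared with a column kit for small samples, and 6.1 ng of total RNA was amplified to cDNA with a whole-transcriptome kit for very small inputs and labelled with Cy3. The labels do not say how many embryos were pooled, or whether the 3 populations of a genotype came from the same embryos. An input this small requires strong amplification, which adds variation to transcripts present in few copies. All arrays lay on 1 slide and were scanned together, wild type in slide row 1 and Satb1-null in slide row 2, so slide row and genotype cannot be told apart.

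The deposited scanner files give the intensity of each spot on a linear scale. Per the file headers they were made with Agilent Feature Extraction 10.10.1.1, and the submitters' processing notes name version 10.10. The intensity used is the signal of the green channel that the column names of the scanner files call processed. The authors also deposited a table of processed values in the series matrix. Set against the scanner files, each column of that table equals the processed signal times a constant per array, between 5.71 and 8.77, so its values are a linear intensity as well. The column medians were 200.1, 140.2, 120.7, 165.3, 145.6 and 124.9 for wild type HSC, LMPP and CLP and null-labelled HSC, LMPP and CLP. The basis of those constants stays unknown. No direction is involved, since the arrays have 1 channel, and genes were not centred.

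Each array held 62976 spots, of which 3671 control spots were left out, as were spots with an outlier mark (154 to 181 per array). The remaining values were turned to log2 and centred by subtracting the array's 75th percentile over non-control spots, and spots of 1 probe were averaged. The 55681 probes were named through their accession in the reference table of assembly GRCm38.p6, which was used only for names and for membership of the X chromosome, the Y chromosome or an autosome. This named 27235 probes of 20660 genes and left 28446 unnamed, of which 16194 carry a genomic interval as their name. For the 5476 genes with more than 1 probe, the probe brightest over the 6 arrays was used. A gene counted as detected where the scanner software called its spots well above background, and 15183 genes were detected on at least 1 array and 11089 on all. The median SD of log2 values over repeated spots of a probe was between 0.0790 and 0.0856 on the 6 arrays.

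A comparison is the difference of log2 values of 2 arrays, for genes well above background on the brighter array. Where the dimmer array was not well above background, the difference is a lower bound, taken against the higher of the gene's own value and the lowest signal well above background on that array (between -4.19 and -3.99 on the centred scale), and is written with "at least" or "no less than". A gene past a 2-fold difference was counted, and no test was made between 2 single arrays. A genotype difference common to the 3 populations was tested with limma (lmFit and eBayes) in a fit of genotype and population over the 6 arrays, added after the data were seen, for the 13012 genes well above background on at least 3 arrays. In it, values not well above background were raised to the array's lowest signal well above background where they lay below it. The populations of a genotype may share embryos, so the p-values of the fit rest only on the spread between these arrays. That spread, before the moderation by eBayes, is how far the genotype difference varies between the 3 populations. A genotype difference confined to 1 population therefore adds to it. The comparisons are Satb1-null against wild type within each population, LMPP against HSC and CLP against LMPP within each genotype, the count of genes past 2-fold the same way in all 3 populations, and correlations across genes well above background on all 4 arrays involved. For 30 gene lists with 442 genes, 432 of them matched to a named probe, the median difference was set against 10000 random lists of the same size matched on mean brightness in 10 bins. A list was called apart below the 2.5th or above the 97.5th percentile, as a description of these arrays, and lists with under 4 measured genes have values only. The lists cover stem cell, early lymphoid, B, T, natural killer, granulocyte, macrophage, dendritic, megakaryocyte, erythroid, mast cell, hepatocyte and endothelial genes, and pathways such as the cell cycle, p53, interferon, Notch, Wnt and V(D)J recombination. Some genes stand in more than 1 list.

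Genes named were Satb1 and the sort markers, the 10 highest and 10 lowest differences per comparison among genes measured on both arrays, up to 5 bounds each way, list members past 2-fold (up to 4) with up to 2 bright members that did not pass, up to 10 genes each way in all 3 populations, and the sex-linked genes. Clone-like names were counted and not named. The lists, the comparisons, this rule and most alternatives were fixed before the data were examined. Other genes named, and the added alternatives, were chosen after the data were seen, as said where they appear.

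The alternatives chosen then were median centring, the 75th percentile over probes detected on all arrays, quantile normalization, normexp background correction with quantile normalization, the authors' processed values, genes well above background on both arrays, no detection filter, the mean over a gene's probes, thresholds of 1.5-fold and 3-fold, leaving out each population from the count over all 3, and unmatched random lists. The normexp alternative used the median spot signal with an offset of 50, because the files hold no mean signal column. A few genes that the rule for named genes picks are not reported here. Added alternatives left out X- and Y-linked genes, the dimmest 25% of genes, or genes at least 4-fold higher on the wild type CLP than on the wild type HSC array.

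The procedure was tested on simulated data made from the arrays' own levels with noise of SD 0.2 added to each array. The scanner error of a difference between 2 arrays had a median of 0.205. The spread of the real differences between genotypes was larger (SD from the median absolute deviation 0.468 in HSC, 0.376 in LMPP and 0.575 in CLP), so the shares given for single populations cover technical noise only. There, changed genes were drawn only from genes more than 4 (log2) above the array's lowest signal well above background. Their recovery therefore says nothing of dim genes. For HSC, run on 20659 genes, it recovered 100% of genes changed 4-fold, 96% changed 3-fold and 12% changed 1.5-fold, and called 0.0635% of unchanged genes. For LMPP, on 20659 genes, the shares were 100%, 98%, 6% and 0.00978%, and for CLP, on 20660 genes, 100%, 100%, 4% and 0.00978%. Unchanged lists fell outside the limits in 3.5%, 5.5% and 4.5% of draws, and lists shifted by 0.3 were called in 92%, 86% and 86%. The unchanged lists were drawn at random from the same genes as the reference lists, with independent noise. Their share outside the limits was therefore set by the limits. It is no rate of false calls for real lists, whose genes may vary together. The fit over 6 arrays, on 13012 genes simulated with their residual SDs after the moderation by eBayes, called 83% of genes changed 4-fold, 3% changed 2-fold and 0.0781% of unchanged genes. The noise there was normal, and simulated values were not raised to the lowest signal well above background. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1 for normexp and the fit over 6 arrays.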

Results

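Satb1 is a chromatin organiser first studied in thymocytes, and the series set out to find genes that depend on it in the earliest lymphoid progenitors. RNA came from fetal liver at E18.5 (embryonic day) of mice labelled Satb1-null and of their wild type littermates, on a C57BL6/J background. Each genotype gave 3 sorted populations. The first, enriched for haematopoietic stem cells (HSC), lacked lineage markers and Flt3 and carried high Kit and Sca-1. The second, enriched for lymphoid-primed multipotent progenitors (LMPP), differed from it by carrying Flt3. The third, enriched for common lymphoid progenitors (CLP), had low Kit, low Sca-1 and the IL-7 receptor. Each of the 6 groups had 1 array, so no difference between 2 arrays has a replicate check or a p-value. P-values are given only for a fit over all 6 arrays. The number of arrays limits the precision. Between 52.4% and 57.7% of the spots of an array were well above background, between 12579 and 13205 genes were detected per array, and no spot was saturated. Differences are log2 values, the array labelled Satb1-null (null-labelled below) minus the wild type array of the same population, so that 1 is a 2-fold difference. The scanner's own error of a difference had a median of 0.205, which does not include variation between animals, sorts or amplifications.

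The targeted gene was examined first. The 1 Satb1 probe was well above background on all 6 arrays. In wild type its level relative to the 75th percentile of the array was -0.03 in HSC, 2.0 in LMPP and 0.71 in CLP, and on the null-labelled arrays -0.59, 1.96 and 0.65. The differences were therefore -0.56, -0.04 and -0.06, of which those of LMPP and CLP were within the scanner error. The LMPP difference turned to 0.01 with the 75th percentile over detected probes and with the values the authors processed, and to 0.04 with normexp. The position of this probe relative to the removed part of the gene is not given in the sources used here, so the probe does not check the labels. Among the sort markers, Flt3 was highest in LMPP and Il7r in CLP on both sets of arrays. Flt3, the cytokine receptor that separates LMPP from HSC, stood at 1.18, 3.21 and 0.85 in wild type HSC, LMPP and CLP and at 1.35, 3.32 and 1.78 on the null-labelled arrays. Il7r, the IL-7 receptor chain used to sort CLP, stood at -2.64, -0.51 and 1.61 in wild type and at -1.71, 0.12 and 1.55 on the null-labelled arrays. Kit was lower in CLP than in LMPP, at 4.41, 4.56 and 2.79 in wild type and 4.63, 4.38 and 3.74 on the null-labelled arrays. Ly6a, which encodes Sca-1, stood at 0.29, 1.12 and 0.21 in wild type and 0.35, 0.14 and -0.50 on the null-labelled arrays.

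**Figure D1:**
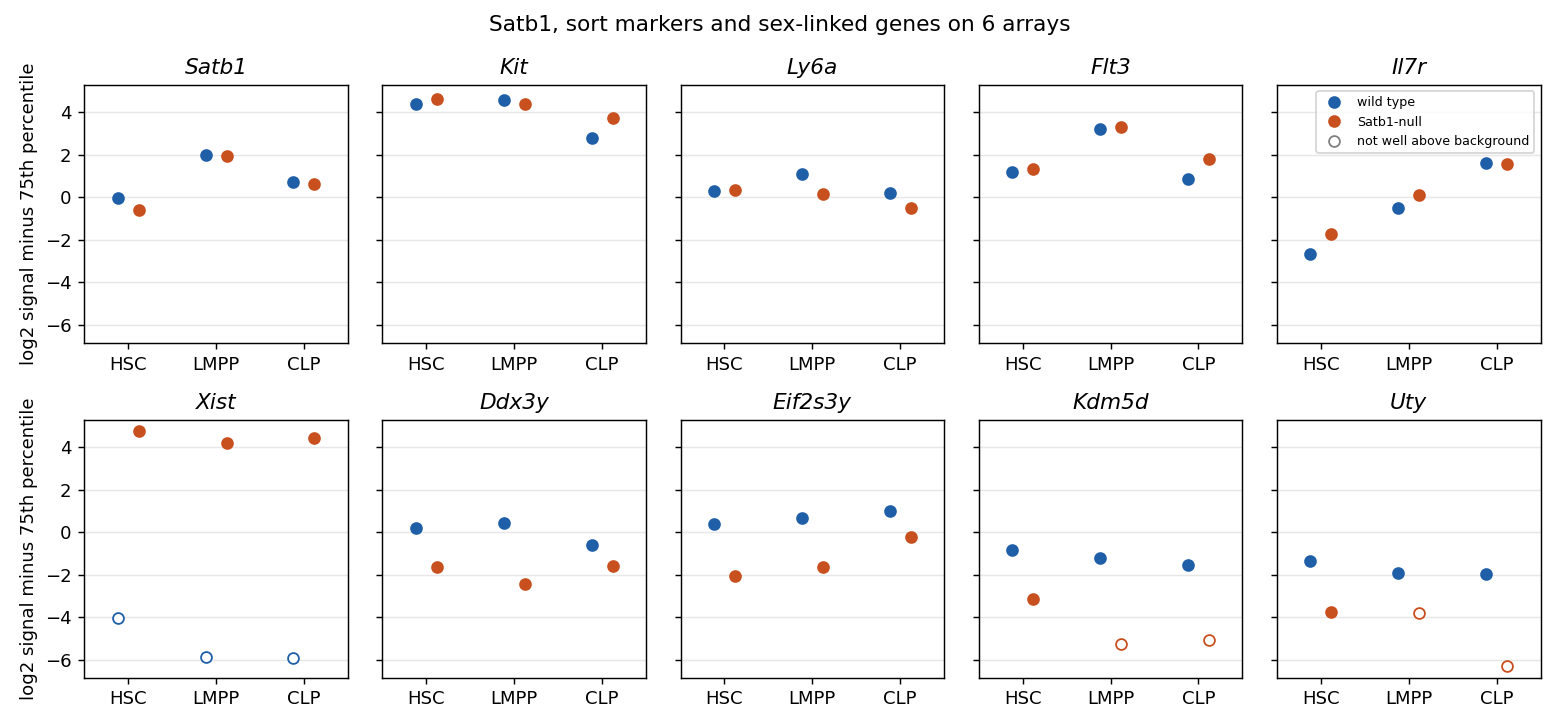
Level of Satb1, the sort markers and sex-linked genes (log2 signal minus the 75th percentile of the array) in HSC, LMPP and CLP, with 1 point per array, blue for wild type and orange for null-labelled, and open points for values not well above background. Satb1 lies at 2.0 and 1.96 on the LMPP arrays, and the Xist probe shown is well above background only on the 3 null-labelled arrays.

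The sex-linked genes differed in the same direction in each population. Xist, the RNA that silences an X chromosome in female cells, stood at 4.74, 4.18 and 4.45 on the null-labelled HSC, LMPP and CLP arrays by the brighter of its 2 named probes. Neither was well above background on any wild type array, which made Xist at least 436-fold, 298-fold and 382-fold higher by the brighter probe. Of 5 further probes that only the files name as Xist, 2 were well above background on the wild type HSC array, and the smallest difference of the 5 there was 2.77. Y-linked genes were lower on the null-labelled arrays, where a negative bound means that far below 0 or further. Eif2s3y differed by -2.43, -2.32 and -1.23, Ddx3y by -1.83, -2.88 and -0.97, Kdm5d by -2.28, by at least -2.78 and by at least -2.63, and Uty by -2.40, by at least -1.90 and by at least -2.20. Zfy1 and Zfy2 were not well above background on any array. The median of the list of sex-linked genes was -2.28 in HSC, -2.32 in LMPP and -1.23 in CLP, the last with a mean of 0.07 because of Xist. The wild type arrays filled slide row 1 and the null-labelled arrays slide row 2 of a single slide. Genotype label, sex-linked signal and slide row therefore went together in every comparison of genotypes.

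In HSC, genes of the B lineage, of granulocytes and monocytes and of erythroid cells were higher on the null-labelled array, together with immediate early genes, and genes of the T lineage were lower. Of the 15 B lineage genes measured, 6 were at least 2-fold higher and none lower, with a median of 0.91 (0.44 with genes at their bounds). They included Vpreb1, a component of the surrogate light chain (at least 4.86), Pou2af1, a B cell coactivator (3.46), Pax5 (1.70) and Spib (at least 1.63), while Bcl11a (0.39) and Cd24a (0.33) did not pass 2-fold. Of 13 erythroid genes 4 were higher and 1 lower (median 0.52), among them Car1 at 2.01, the alpha globin Hba-a1 at 1.63 and Ermap at -1.03. The other 2 Ermap probes went the opposite way (0.98 and 1.18), and its mean over probes was 0.38. The 25 granulocyte and monocyte genes had a median of 0.41 with 1 past 2-fold, Cebpe at 1.5, beside Mpo at 0.27. The early lymphoid list (18 genes, median 0.45) had 2 genes higher and 1 lower, and its recombinase genes went apart, Rag1 at no less than 1.44 and Rag2 at -1.10. Each rests on 1 probe, since the other probe of either gene was not well above background on either HSC array. Of 13 T lineage genes 1 was higher and 3 were lower, Cd4 (-1.07), Cd3e (-1.05) and Cd28 (-1.04), with a median of -0.65. Immediate early and heat shock genes (19 genes, median 0.45) included the heat shock gene Hspa1a (2.58) and Atf3 (1.31). The mast cell, basophil and eosinophil list had a median of 0.59 (9 genes, Cma1 1.03), the hepatocyte list 0.61 (0.56 with bounds, 10 genes, Alb at least 1.38), the endothelial and stromal list -0.79 (-0.42 with bounds, 8 genes, Cxcl12 -2.40, Stab2 at least -1.44) and the interferon list -0.20 (16 genes, Xaf1 -1.27, Ifit3 1.05).

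Among single genes in HSC, the 10 highest of those measured on both arrays were Chst1 (4.24), Olfr11 (3.92), Tmem132a (3.73), Olfr920 (3.72), Bcl3 (3.71), Olfr1036 (3.59), Rsph1 (3.54), Exd1 (3.50), Epha2 (3.47) and Pou2af1 (3.46). The 10 lowest were Wnt5b (-3.64), Fam184b (-3.24), Cdkl3 (-3.04), Enho (-2.89), Vamp1 (-2.69), Ica1l (-2.58), Mirg (-2.57), Tyms (-2.55), Cxcr6 (-2.44) and Prdm9 (-2.44). Wnt5b is a secreted Wnt ligand and Tyms makes thymidylate for DNA synthesis. Against a wild type array not well above background, the largest lower bounds after Xist were Olfr1316 (5.03), Nkx2-5 (4.99), H60b (4.89) and Vpreb1 (4.86). The largest in the other direction were Bco2 (-3.81), Pou5f2 (-3.70), Has3 (-3.69), Spic (-3.65) and Gsg1 (-3.62). Of 13939 genes compared, 1174 were at least 2-fold higher and 815 lower, and 752 of these 1989 rest on a lower bound. The median over all genes was 0.14, so the list medians above are to be read against that shift. The split of 59.0% higher became 73.5% (1625 higher, 585 lower) with median centring, 46.9% (933 and 1057) with the 75th percentile over detected probes and 47.1% (1772 and 1994) without a detection filter, and with the authors' processed values it was 49.4% (982 and 1006). The lists described above stood apart from matched random lists, the higher ones at percentiles from 97.81 to 99.98 and the lower ones at 0 to 2.34. Of these 11 lists, 6 lost that standing under at least 1 alternative: early lymphoid, B lineage, T lineage, hepatocyte, endothelial and interferon. The lists that did not stand apart had medians as follows: HSC genes (0.30), Notch targets (0.29), NK and innate lymphoid (0.36), macrophage (0.79, or 0.43 with bounds), dendritic cell (-0.15), megakaryocyte (0.25), cell cycle (0.26), CDK inhibitors and quiescence (0.34), p53 targets (0.25), Bcl2 family (0.23), MHC class II (0.27), Hox genes (-0.26), Wnt targets (0.12), chromatin partners (0.25), Satb1 T cell loci (0.15), V(D)J recombination (-0.27), ribosomal proteins (0.03), oxidative phosphorylation (0.12) and glycolysis (0.31). The dendritic, Wnt, ribosomal and oxidative phosphorylation medians changed sign with the centring. The means of the dendritic cell (0.18), Wnt (-0.25) and V(D)J (0.22) lists had the opposite sign.

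In LMPP, genes of several mature blood lineages were higher on the null-labelled array and interferon response genes were lower. Of the sort markers, Ly6a differed by -0.98 there, Kit by -0.18 and Flt3 by 0.11. Whether both LMPP sorts held the same cells was not decided. Of 13 erythroid genes 6 were at least 2-fold higher and none lower (median 0.81), led by Alas2, the first enzyme of haem synthesis in red cells (3.03), the anion exchanger Slc4a1 (2.56) and Hba-a1 (2.40). Of 15 megakaryocyte genes 7 were higher (median 0.38), among them Vwf (2.70), Itga2b (2.33), Ppbp (1.79) and Pf4 (1.56). Of 7 mast cell, basophil and eosinophil genes 5 were higher (median 1.83, or 1.5 with genes at their bounds), among them Epx (2.42), Il1rl1 (1.83) and Prg2 (1.5). Macrophage genes had a median of 1.59 (0.87 with bounds) with 3 of 8 higher, Marco at 2.65, Vcam1 at no less than 2.39 and Cd5l at no less than 2.02. Granulocyte and monocyte genes had a median of 0.31 with 4 of 25 higher, Ms4a3 (1.65), Elane (1.43), Fcnb (1.23) and S100a8 (1.14), while Mpo was 0.05. Of 16 B lineage genes 7 were higher (median 0.78, or 0.68 with bounds), with Pou2af1 at least 4.03, Bst1 at least 2.75, the surrogate light chain gene Igll1 at least 2.67 and Vpreb1 at 2.34. The interferon response list had 5 of 16 genes lower and none higher (median -0.80), among them Ifit3 (-2.34), Usp18 (-1.63), Ifi44 (-1.55) and Ifit1 (-1.42). The Hox list had a median of -0.48 over 10 genes, with Hoxa10 at -1.56, Hoxa9 at -0.48 and Hoxb4 at 1.25. Natural killer (0.33, 14 genes, Gzma at least 1.91), MHC class II (0.35, 9 genes, H2-Eb1 2.02, Cd74 1.33), p53 target (0.42, 11 genes, Cdkn1a 1.25) and immediate early lists (0.14, 19 genes, Hspa1a 1.88) were also higher.

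Among single genes in LMPP, the 10 highest were Kazn (3.64), Nova1 (3.51), Sox1ot (3.48), Ifitm5 (3.26), Cyp2j6 (3.21), Plcb1 (3.11), Lama5 (3.09), Paqr4 (3.06), Zfp428 (3.05) and Alas2 (3.03). The 10 lowest were Gdap1l1 (-3.16), Ddx3y (-2.88), Crispld1 (-2.81), Evpl (-2.71), Scai (-2.71), Kbtbd3 (-2.69), Spem1 (-2.44), Tmem132a (-2.44), Ifit3b (-2.34) and Ifit3 (-2.34). Apart from Xist, the largest lower bounds were Kcp (4.94), Fcrl1 (4.76), Fbln2 (4.65) and Mcm9 (4.54) among higher genes and Pcdh8 (-4.40), Trim7 (-4.06), Rab15 (-3.49), Evi2 (-3.43) and Fxyd6 (-3.13) among lower genes. Of 13364 genes compared, 773 were at least 2-fold higher and 550 lower, of which 603 rest on a bound. The median over all genes was -0.04. The split of 58.4% higher became 75.5% (182 and 59) with normexp and 72.4% (368 and 140) at a 3-fold threshold, and was lowest at 51.1% (1602 and 1532) at a 1.5-fold threshold. The higher lists stood at percentiles from 97.78 to 100 of matched random lists and the lower ones at 0 to 0.63. Natural killer, macrophage, MHC class II and immediate early lists lost their standing under at least 1 alternative. The lists that did not stand apart had medians as follows: HSC genes (0.01), early lymphoid priming (-0.09), T lineage (-0.03), Notch targets (0.23), dendritic cell (0.07), hepatocyte (-0.36), endothelial and stromal (0.11), cell cycle (-0.01), CDK inhibitors and quiescence (0.12), Bcl2 family (-0.21, or -0.11 with bounds), Wnt targets (0.33), chromatin partners (-0.07), Satb1 T cell loci (0.15), V(D)J recombination (-0.10), ribosomal proteins (-0.05), oxidative phosphorylation (-0.04) and glycolysis (-0.01). The T lineage, cell cycle, glycolysis and oxidative phosphorylation medians changed sign with the centring or normalization, the dendritic cell median with the mean over probes. The means of the T lineage (0.04), endothelial (-0.22), hepatocyte (0.00) and Satb1 T cell loci (-0.01) lists had the opposite sign.

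In CLP, genes of V(D)J recombination and of the B lineage were higher on the null-labelled array, and megakaryocyte genes were lower. Kit was higher there by 0.95, and Flt3 by 0.93 with its brighter probe and 0.10 with the other. Whether both CLP sorts held the same cells was not tested. Of 10 V(D)J recombination genes 6 were at least 2-fold higher and none lower (median 1.43), among them the recombinase genes Rag1 (2.40) and Rag2 (1.88) and the end joining genes Xrcc4 (1.82) and Nhej1 (1.64). Probes of this list disagreed for Atm, which was 1.58 by its brighter probe and -2.18 by the other. Rag1 was higher by both its probes, at 2.40 and 1.18. The list median was 0.40, no longer apart, with the mean over probes. Of 19 B lineage genes 6 were higher (median 0.66), with Bst1 at 3.07, Irf4 at 2.63 and Ebf1, a factor that specifies B cells, at no less than 2.19. The early lymphoid list (19 genes, median 0.54) had 5 higher, the RAG genes included, with Il12rb2 at no less than 1.79 and Lax1 at 1.17. Its call was lost with the mean over probes. The megakaryocyte list had a median of -0.43 over 16 genes, with Gp6 at least -3.63 and Gp5 at least -2.76. HSC genes had a median of -0.31 over 21 genes (-0.27 with bounds), with 3 higher and 3 lower, Hlf at 2.45, Hoxb4 at least -2.05 and Prdm16 at least -1.93, and the median was 0.12 over genes measured on both arrays. Mast cell (0.57, 9 genes, Mcpt8 1.94), MHC class II (0.63, 9 genes, H2-Oa 2.55) and immediate early lists (0.39, 19 genes, Hspa1a 1.61) were also higher.

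Among single genes in CLP, the 10 highest were Zcwpw1 (4.82), Setd4 (4.58), Shtn1 (4.53), Fzd9 (3.97), Klhl1 (3.93), Zkscan7 (3.93), Dlat (3.89), Dgke (3.89), Evi2 (3.81) and Sytl1 (3.78). The 10 lowest were Shfl (-5.57), Ramp3 (-5.03), Gpd1 (-4.66), Ephb4 (-4.45), Spock2 (-4.40), Pank1 (-4.14), Prss8 (-4.12), Hdac8 (-4.12), Peg10 (-4.11) and Odf3b (-4.08). Shfl is an interferon-induced antiviral gene and Peg10 an imprinted gene. Apart from Xist, the largest lower bounds were Fstl1 (5.08), Dtna (5.04), Khdc1b (4.99) and Slc5a9 (4.59) among higher genes and Chst1 (-6.01), Kank1 (-5.85), Comp (-4.72), Saysd1 (-4.55) and Trpm2 (-4.54) among lower genes. CLP had the highest counts of the 3 populations, with 1635 genes at least 2-fold higher and 1137 lower of 13669 compared, of which 896 rest on a bound. The median over all genes was 0.03. The higher lists stood at percentiles from 98.83 to 99.94 of matched random lists and the lower ones at 0.21 to 1.72. Besides the V(D)J and early lymphoid lists, the HSC, mast cell, MHC class II and immediate early lists lost their standing under at least 1 alternative. The lists that did not stand apart had medians as follows: T lineage (0.03), Notch targets (-0.31), NK and innate lymphoid (0.32), granulocyte and monocyte (-0.12), macrophage (0.13), dendritic cell (-0.10), erythroid (0.04), hepatocyte (0.67), endothelial and stromal (-0.41), cell cycle (0.12), CDK inhibitors and quiescence (0.19), p53 targets (-0.05), Bcl2 family (0.08), interferon response (0.02), Hox genes (-0.61), Wnt targets (0.35), chromatin partners (-0.11), Satb1 T cell loci (0.19), ribosomal proteins (-0.20), oxidative phosphorylation (0.10) and glycolysis (0.05). Of these, the T lineage, dendritic, erythroid, interferon, glycolysis, CDK inhibitor, Wnt, chromatin partner and Notch medians changed sign under at least 1 alternative. The means of the T lineage (-0.05), Notch (0.10), erythroid (-0.11), endothelial (0.08), p53 (0.08) and interferon (-0.04) lists had the opposite sign.

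**Figure D2:**
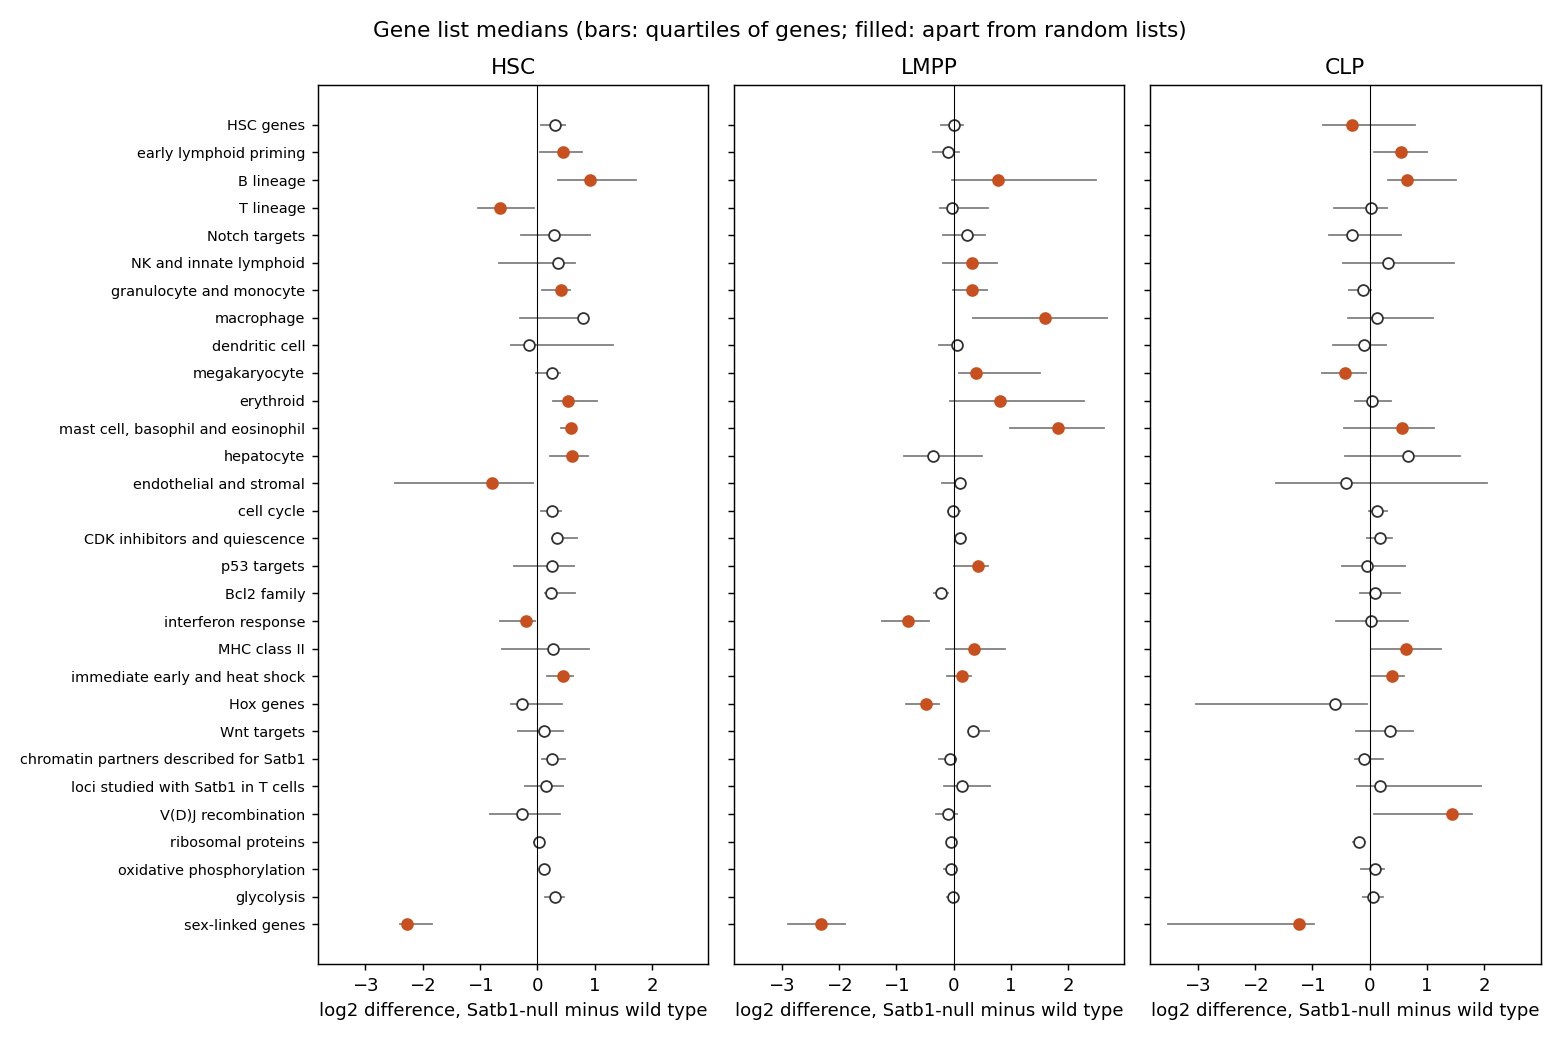
Median log2 difference, null-labelled minus wild type, of each gene list (points) with the quartiles of its genes (bars) in HSC, LMPP and CLP, where filled points stand apart from random lists matched on brightness. B lineage medians are 0.91, 0.78 and 0.66 (0.44, 0.68 and 0.66 with genes at their bounds), and the erythroid median is 0.52 in HSC, 0.81 in LMPP and 0.04 in CLP.

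Across the 3 populations, 27 genes were at least 2-fold higher in each and 21 at least 2-fold lower, of 12347 compared in all. After Xist, the named higher genes were Epha2, an ephrin receptor (3.47, 2.36 and 2.06 in HSC, LMPP and CLP), Klhl1 (1.95, 2.13 and 3.93), Pou2af1 (3.46, at least 4.03 and 1.89), the phospholipase gene Plcb1 (1.88, 3.11 and 2.26), Hspa1a (2.58, 1.88 and 1.61), Tctex1d1, Aoc3, Klra2 and Ccdc92b. The named lower genes were the Y-linked Kdm5d, Uty and Eif2s3y, the X-linked Tmem35a, and Plekhb1 (-2.03, -1.64 and at least -3.45), Trip4 (-2.35, -1.57 and -2.02), the interferon-induced Ifit3b (-1.67, -2.34 and -1.45), Colq (-1.75, -1.54 and -1.23), Stab2 and Brinp2. With the genotype labels of 1 population exchanged, the counts were 13, 21 and 19 for higher and 13, 14 and 15 for lower. Independent lists of these sizes would share 3.32 and 1.52 genes. These figures take every gene as equally likely to pass 2-fold, while dim genes passed more often. All counts with exchanged labels exceed them too, so an excess over them is no sign of a common effect. Across genes, which are not independent replicates, the genotype difference in HSC correlated with that in LMPP at r = 0.102 (rho 0.104) and with that in CLP at r = 0.0779 (rho 0.111), and LMPP with CLP at r = -0.00728 (rho -0.0277). These 3 correlations were added after the data were seen, as was a fit of genotype and population over all 6 arrays with limma. In that fit, with 13012 genes tested and 2 residual degrees of freedom, Xist was the 1 gene with a Benjamini-Hochberg adjusted p under 0.05 (difference at least 8.52, adjusted p = 0.00442), and no gene was lower. Xist was not well above background in wild type, so its difference is a bound, and its p rests partly on values set to the array's lowest signal well above background. At an unadjusted p under 0.05 there were 387 higher and 339 lower genes, 726 in all, where 651 are due with no difference at all.

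From HSC to LMPP, both genotypes had lower stem cell and mast cell genes and higher early lymphoid genes. In wild type the HSC genes had a median of -0.62 (22 genes, 6 lower and 1 higher, Mllt3 -2.17, Vwf -1.70), and on the null-labelled arrays -0.59 (22 genes, Tek -2.20, Gata2 -1.91). Early lymphoid genes had a median of 1.04 in wild type, with 9 of 18 higher, among them the chemokine receptor gene Ccr9 (3.81), Lax1 (2.26), Il7r (2.13) and Notch1 (2.10), and of 0.79 on the null-labelled arrays, with Ccr9 at 2.55, Rag2 at 2.5 and Flt3 at 1.98. Mast cell genes had medians of -3.05 and -3.17, with Cpa3 at least -5.63 in wild type and -5.02 on the null-labelled arrays. Erythroid genes were lower (-0.76 and -0.48), and dendritic cell (0.92 and 1.09, or 0.91 and 0.84 with bounds), MHC class II (1.12 and 1.91), V(D)J (0.64 and 0.69, the first 0.63 with bounds) and cell cycle genes (0.59 and 0.30) were higher. Interferon response and Hox genes stood apart in wild type (0.71 and 0.72) and not on the null-labelled arrays (0.07 and 0.08). T lineage, ribosomal, oxidative phosphorylation and chromatin partner genes stood apart on the null-labelled arrays (0.56, 0.40, 0.35 and -0.29) and not in wild type (0.14, 0.45, 0.47 and 0.22). The ribosomal and oxidative phosphorylation medians were higher in wild type, and no difference between the genotypes in these shifts was tested. The granulocyte list stood apart in wild type with a median of -0.02, which became 0.25 with median centring, so no direction is given for it. These lists stood at percentiles of 98.12 or above, or of 0.57 or below, of matched random lists in wild type, and at 98.75 or above, or 0.19 or below, on the null-labelled arrays. The granulocyte, Hox and V(D)J calls in wild type and the T lineage, cell cycle, chromatin partner and oxidative phosphorylation calls on the null-labelled arrays were lost under at least 1 alternative.

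Among single genes from HSC to LMPP in wild type, the 10 highest were Ccr9 (3.81), Emp1 (3.38), Oscp1 (3.30), Mn1 (3.29), Paqr5 (3.17), Cox6a2 (3.11), Ccl3 (3.11), St8sia1 (3.06), Tmem132a (3.0) and Ctss (2.95), and the 10 lowest were Il1rl1 (-5.40), Slc7a8 (-3.62), Gda (-3.55), Spic (-3.32), Tpsb2 (-3.24), Icam4 (-3.18), Hdc (-3.05), Alas2 (-2.88), Tgm2 (-2.81) and Ncoa1 (-2.79). The largest bounds were Pcdh8 (4.44), Evpl (4.37), Trim7 (4.10), Tmem268 (3.82) and Rab15 (3.71) among higher genes and Cpa3 (-5.63), Igsf3 (-4.26), Nectin1 (-4.09), Cma1 (-4.09) and Nbea (-3.95) among lower genes. On the null-labelled arrays the 10 highest were Wnt5b (5.46), Zfp428 (3.74), Sox1ot (3.72), Tlcd2 (3.54), Bbs1 (3.41), Slc38a6 (3.39), Dnaaf1 (3.38), Zfp341 (3.12), Ctss (3.05) and Whrn (2.96), and the 10 lowest were Cpa3 (-5.02), Tpsb2 (-4.42), Zc3h8 (-4.17), Ramp3 (-4.08), Eps8l3 (-3.71), Il1rl1 (-3.70), Tgm2 (-3.68), Kbtbd3 (-3.60), Dbndd1 (-3.58) and Akain1 (-3.44). The largest bounds there were Myl4 (5.59), Kcp (4.94), Fcrl1 (4.75), Fbln2 (4.65) and Mcm9 (4.54) among higher genes and Olfr11 (-5.21), Cma1 (-5.06), Olfr1316 (-4.99), Nkx2-5 (-4.95) and H60b (-4.85) among lower genes. Of 13712 genes compared in wild type 1021 were higher and 919 lower, and of 13629 on the null-labelled arrays 991 were higher and 1120 lower. In wild type the median over all genes was 0.22, and the split of 52.6% higher became 78.9% (2104 and 564) with median centring, 29.1% (593 and 1446) with the 75th percentile over detected probes and 28.3% (581 and 1474) with the authors' processed values. Across 11617 genes the change in wild type correlated with that on the null-labelled arrays at r = 0.317 (rho 0.306).

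From LMPP to CLP, both genotypes had lower stem cell and Hox genes and higher B lineage genes, and genes of mature myeloid and erythroid cells were also higher. On the wild type CLP array Hba-a1 stood at 8.83, S100a8 at 7.85 and Slc4a1 at 7.82. Flt3 stood at 0.85 there, below 1.18 in wild type HSC, but at 1.78 against 1.35 on the null-labelled arrays. Which cells carried these genes was not tested, so the changes are between sorts and need not be changes within lymphoid cells. HSC genes had medians of -1.42 in wild type (22 genes, 13 lower) and -1.92 on the null-labelled arrays (-1.85 with bounds, 21 genes, 14 lower), with Procr at -5.88 and at least -6.06. The Hox medians were -3.07 in both (-2.38 and -3.04 with bounds), with 9 of 10 and 8 of 9 genes lower and Hoxa9 at -5.59 and -4.62. B lineage medians were 2.18 and 1.77 (1.54 and 1.72 with bounds), with 11 of 18 and 13 of 20 genes higher, Vpreb1 at 5.24 in wild type and Vpreb3 at no less than 3.47 on the null-labelled arrays. Erythroid genes had medians of 3.84 and 2.68, with Slc4a1 at 6.40 and 4.05. Mast cell, basophil and eosinophil genes had medians of 6.0 (5.06 with bounds) and 4.12, with Il1rl1 at 6.83 and 4.80. Granulocyte and monocyte genes had medians of 2.53 and 1.85, with 20 of 25 genes higher in each genotype and Fcnb, a neutrophil lectin, at 5.58 and 4.37. Macrophage (3.51 and 2.29, or 3.26 and 2.24 with bounds), megakaryocyte (2.39 and 0.72, the first 2.35 with bounds), dendritic cell (1.56 and 1.46, the first 1.44 with bounds), natural killer (0.61 and 0.92, the first 0.45 with bounds) and cell cycle genes (0.53 and 0.70) were higher. Early lymphoid (-1.17 and -0.69), interferon (-1.73 and -1.0) and ribosomal genes (-0.50 and -0.59) were lower, and Notch target (-1.42) and hepatocyte genes (-1.18, or -0.96 with bounds) were lower on the null-labelled arrays, against medians of -0.39 and -0.49 that did not stand apart in wild type, a difference that was not tested. These lists stood at percentiles of 98.3 or above, or of 0.13 or below, in wild type, and at 99.39 or above, or 0.95 or below, on the null-labelled arrays. The B lineage, natural killer, dendritic and ribosomal calls in wild type, and the early lymphoid, Notch, dendritic and hepatocyte calls on the null-labelled arrays, were lost under at least 1 alternative.

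Among single genes from LMPP to CLP in wild type, 9 of the 10 highest were Gda (7.59), Epx (6.99), Il1rl1 (6.83), Alas2 (6.44), Slc4a1 (6.40), Pklr (6.11), Ear6 (6.08), Gapt (5.99) and Ncam1 (5.99), and 9 of the 10 lowest were Procr (-5.88), Prrg4 (-5.72), Hoxa9 (-5.59), Rps6ka6 (-5.55), Fzd9 (-5.30), Fbln1 (-5.25), Gimap8 (-5.23), Hlf (-5.09) and Krt18 (-5.00). The largest bounds were Btnl10 (7.47), Olfml2b (7.28), Lrg1 (6.99), Aqp3 (6.97) and Prss34 (6.67) among higher genes and Fstl1 (-8.00), Slc18a1 (-7.03), Bdh1 (-5.86), Ddx4 (-5.71) and Tceal5 (-5.61) among lower genes. On the null-labelled arrays 9 of the 10 highest were Gas7 (5.79), Prss34 (5.68), Slc38a5 (5.49), Gda (5.07), Slc40a1 (4.97), Lrg1 (4.94), C3 (4.94), Chil1 (4.91) and Chil3 (4.80), and the 10 lowest were Ctla2b (-5.53), Cnrip1 (-4.94), Adgrl4 (-4.82), Zfp428 (-4.74), Zfp503 (-4.74), Tceal5 (-4.66), Hoxa9 (-4.62), Shfl (-4.61), Gimap8 (-4.54) and Tnfsf10 (-4.41). The largest bounds there were Il6 (6.85), Fam83g (5.92), Add2 (5.85), Abca13 (5.66) and Sox6 (5.49) among higher genes and Wnt5b (-6.19), Procr (-6.06), Hoxa3 (-5.97), Rsad1 (-5.24) and Kcp (-5.09) among lower genes. Of 13654 genes compared in wild type 1985 were higher and 2458 lower, and of 13750 on the null-labelled arrays 2088 were higher and 1984 lower. With median centring the splits became 58.1% higher (2593 and 1869) in wild type and 61.6% (2602 and 1622) on the null-labelled arrays. Across 11201 genes the changes of the 2 genotypes correlated at r = 0.658 (rho 0.561).

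Some genes past 2-fold had a further probe well above background. That probe went the same way for 213 of 344 genes (61.9%) in the HSC genotype comparison, 141 of 215 (65.6%) in LMPP and 344 of 542 (63.5%) in CLP. From HSC to LMPP it did so for 265 of 374 genes (70.9%) in wild type and 247 of 354 (69.8%) on the null-labelled arrays, and from LMPP to CLP for 851 of 1025 (83.0%) and 752 of 901 (83.5%). Genes past 2-fold between genotypes were mostly dim. In the dimmest 25% of genes 24.3%, 22.2% and 29.3% passed 2-fold in HSC, LMPP and CLP, and in the brightest 25% 2.04%, 0.688% and 3.86%. From HSC to LMPP the shares were 21.6% and 4.81% in wild type and 27.4% and 2.41% on the null-labelled arrays. From LMPP to CLP they were 32.8% and 23.2% in wild type and 34.9% and 20.2% on the null-labelled arrays.

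**Figure D3:**
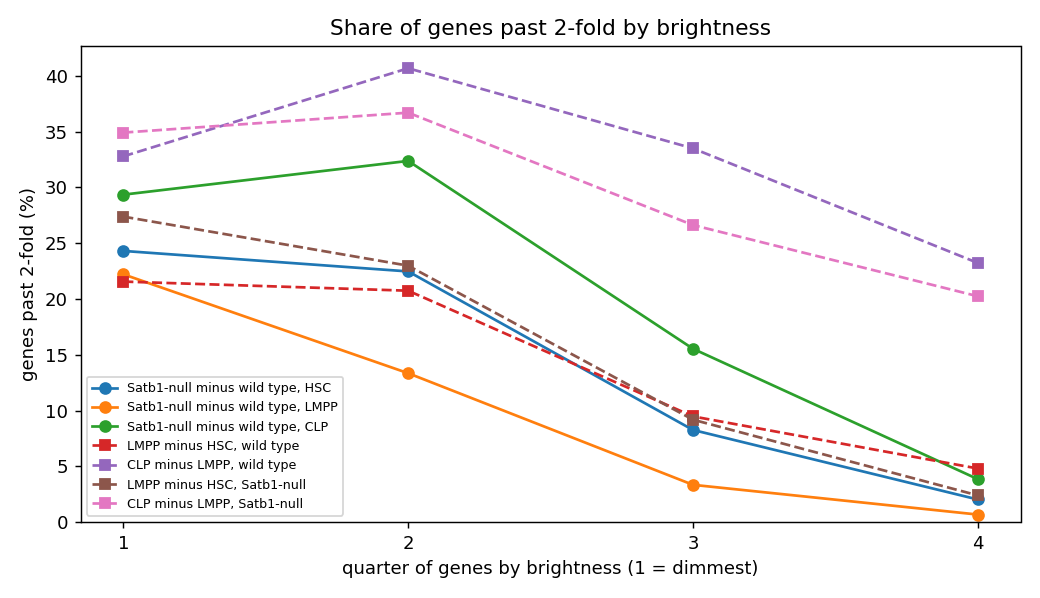
Share of genes past 2-fold (percent) in 4 groups of equal size of genes ordered by brightness, with 1 line per comparison. In the dimmest group the genotype comparisons lie between 22.2% and 29.3% and in the brightest between 0.688% and 3.86%, while HSC to LMPP in wild type goes from 21.6% to 4.81% and LMPP to CLP in wild type from 32.8% to 23.2%.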

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

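The tests of brightness, of exchanged labels and of the shares of other cells were chosen after their results were seen. Those of escape genes, of X-linked genes and of centring were chosen before.

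The megakaryocyte list went opposite ways in LMPP (0.38) and CLP (-0.43), and 35 of the 199 genes named passed 2-fold in opposite directions in different populations. None of these differences between populations was tested, and the named genes were mostly picked for large differences. Among all genes measured on the arrays involved and past 2-fold in both populations, 102 went the same way and 67 opposite ways in HSC and LMPP. The counts were 170 and 120 in HSC and CLP, and 93 and 88 in LMPP and CLP. The 35 named genes follow. In HSC and LMPP, in that order, the genes were Cdkn2c (-1.64 and 1.61), Exd1 (3.50 and -1.09), Gsg1 (-3.62 and 1.23), Ifit3 (1.05 and -2.34), Kbtbd3 (1.51 and -2.69), Rab15 (1.26 and -3.49) and Tmem132a (3.73 and -2.44). In HSC and CLP they were Alb (1.38 and -2.38), Batf3 (1.02 and -2.80), Cd3e (-1.05 and 1.81), Cxcl12 (-2.40 and 3.24), Gpd1 (2.55 and -4.66), H60b (4.89 and -1.86), Ica1l (-2.58 and 2.88), Nhej1 (-1.45 and 1.64), Olfr920 (3.72 and -1.13), Rag2 (-1.10 and 1.88), Ramp3 (2.62 and -5.03), Xaf1 (-1.27 and 1.60) and Xrcc4 (-1.18 and 1.82). In LMPP and CLP they were Crispld1 (-2.81 and 2.01), Gp6 (1.08 and -3.63), Hoxb4 (1.25 and -2.05), Serpina1a (-1.32 and 1.34), Sox1ot (3.48 and -1.12), Trim7 (-4.06 and 1.02) and Zbtb46 (1.83 and -1.74). With a value in each of HSC, LMPP and CLP they were Chst1 (4.24, 3.26 and -6.01), Dgke (-1.43, 1.23 and 3.89), Evi2 (-1.25, -3.43 and 3.81), Evpl (1.29, -2.71 and 1.86), Lta (-1.37, 1.35 and -1.91), Marco (-1.34, 2.65 and 2.01), Vamp1 (-2.69, 1.14 and 2.28) and Wnt5b (-3.64, 1.37 and -2.04). Some of these values are lower bounds.

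Probes without a gene name, which no comparison uses, also held signal: 49 were at least 2-fold higher and 65 at least 2-fold lower in all 3 populations, of 12212 compared. With the labels of HSC, LMPP or CLP exchanged, the counts were 41, 21 and 21 for higher and 22, 68 and 49 for lower. The 5 probes that the files themselves name as Xist were higher on every null-labelled array, with smallest differences of 2.77 in HSC, 2.60 in LMPP and 3.03 in CLP, and 2 of them were well above background on the wild type HSC array.

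The first pattern is high Xist and low Y-linked signal on all 3 null-labelled arrays. Xist switched on in male cells would silence their single X, but the median of X-linked genes minus the autosomal median was -0.0388 at its lowest over the populations, and the lowest bootstrap bound was -0.10. Embryos of different sex behind the genotypes need higher levels of genes that escape X inactivation, and Kdm6a, Kdm5c, Eif2s3x and Ddx3x had a median of 0.49 over 12 differences, 7 of them positive, at percentile 99.87 of matched random lists. A difference of sex may therefore account for these genes. Sex, slide row and genotype label coincide here, so for all other genes a genotype effect stays open, and no fit over these arrays can separate it from the others.

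The second pattern is that genes past 2-fold between genotypes were mostly dim, and that few were shared by the populations. The smallest ratio of the share past 2-fold in the dimmest 25% of genes to that in the brightest 25% was 7.60 over the 3 populations, which restates the pattern and so decides nothing about amplification noise near background, and the share of further probes going the same way was 64.9%, 61.2% and 63.3% in the dimmest 25% and 62.5%, 60% and 69.6% in the brightest, the last over 16, 10 and 46 genes. A common effect of genotype predicts more shared genes with the real labels than with exchanged ones, and there were 27 higher genes against at most 21, and 21 lower genes against at most 15. With 4 arrangements the labels are too few for a share under 0.05. Both counts also contain sex-linked genes, without which they were 25 and 17, and noise and a common effect both stay open.

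The third pattern is the higher level of granulocyte, megakaryocyte, erythroid and mast cell genes on the null-labelled LMPP array. The centring of the arrays is argued against, since another centring shifts all genes alike and cannot move a percentile, and the 4 lists stayed at or above percentile 99.11 under the 2 normalizations that could move it, quantile and normexp. Cells of other lineages could have entered that sort, and Hba-a1 stood at 6.23 there against 3.83 in wild type. The gate removed lineage-positive cells, however, and wild type LMPP had 56 of the 71 list genes well above background (4 stand in another list). With wild type CLP signal standing in for such cells, over genes at least 4-fold higher there than in wild type HSC and over 2-fold higher than in wild type LMPP, the median share needed was 2.74% for 15 granulocyte, 3.46% for 3 mast cell, 5.67% for 9 erythroid and 16.8% for 6 megakaryocyte genes, 6.13 times apart, and 4.22% (quartiles -1.29% and 12.6%) for all 647 such genes. The bound written for this test, 5 times apart beyond the quartiles, was exceeded and would have excluded such cells, but the question is left undecided because that bound assumed that the admixed cells have the wild type CLP profile, a reason found only after the value was seen, and an effect of genotype on lineage genes also stays open and untested.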

How the results depend on the processing

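Tests of genes left out for brightness, sex linkage or a high level in CLP were chosen after the data were seen. The genotype differences of Satb1 moved by less than the scanner error under every alternative run. Of 8763 alternative values of named genes, 7186 moved by less than the scanner error, 1574 by more and 3 reversed, all with the mean over probes: Bst1 from HSC to LMPP on the null-labelled arrays (-1.02), Cdkn1a in CLP (-0.14) and Ermap in HSC (0.38). A reversal was counted only for differences that were past 2-fold before the change of setting. Smaller differences that changed sign are counted by how far they moved. The Cdkn1a mean takes in a probe not well above background on either CLP array, so it is no evidence of a reversal. The Bst1 probes went opposite ways. The brighter rose from -3.64 on the null-labelled HSC array to -1.28 on the LMPP array. The other fell from -1.59 to -5.98, the last not well above background, so -1.02 is not a measured size. The direction of Bst1 there depends on the probe. Settings that treat dim genes differently moved many counts by over 1.5 times, and so did thresholds of 1.5-fold and 3-fold. Low signal over background may limit these data, which these settings do not decide. Except where said, the cause was not tested.

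Counts below are higher then lower genes in HSC, LMPP and CLP, and then in all 3 populations. Normexp, which compresses dim signals, gave 317 and 171, 182 and 59, 510 and 358, and 5 and 3, with 513 and 551 genes from HSC to LMPP and 2402 and 1991 from LMPP to CLP in wild type and on the null-labelled arrays, and correlations of 0.377 and 0.728. Genes measured on both arrays, by construction fewer, gave 739 and 498, 419 and 301, 1067 higher, and 10 and 11, with 1218 from HSC to LMPP on the null-labelled arrays. No detection filter, which adds dim genes, gave 1772 and 1994, 1438 and 1288, 2048 lower, and 70 and 88, with 3639 and 3551 from HSC to LMPP and correlations of 0.159 and 0.484. A 1.5-fold threshold gave 2643 and 1918, 1602 and 1532, 3073 and 2277, and 114 and 103, with 5164 and 4411 genes from HSC to LMPP and 7107 and 6870 from LMPP to CLP in wild type and on the null-labelled arrays. A 3-fold threshold gave 460 and 267, 368 and 140, 773 and 485, and 7 and 3, with 620 and 939, and 2411 and 2133, between the stages. Without the dimmest 25% of genes the counts were 744 and 398, 377 and 204, 1032 and 737, and 15 and 11. Leaving out genes at least 4-fold higher on the wild type CLP than HSC array moved the counts in HSC, LMPP and CLP by less than 1.5 times. Over only 2 populations, genes past 2-fold in both were 117 and 82 without HSC, 206 and 125 without LMPP and 129 and 80 without CLP.

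Of 33 list calls between genotypes 17 were kept under all 6 alternatives that can move a percentile, and of 53 between stages 38. The other 3, which shift all genes of an array alike, cannot end a call. The calls lost, with the percentile they had, are given by setting. With unmatched random lists they were granulocyte LMPP/HSC wild type 10.07, mast cell CLP 95.49, interferon HSC 2.99, MHC class II CLP 96.89, immediate early LMPP 94.53, immediate early CLP 95.73, chromatin partners LMPP/HSC null 6.83, ribosomal proteins CLP/LMPP wild type 7.45 and oxidative LMPP/HSC null 96.84. With quantile normalization they were HSC genes CLP 2.56, hepatocyte HSC 96.28, cell cycle LMPP/HSC null 95.4, Hox genes LMPP/HSC wild type 95.17 and oxidative LMPP/HSC null 94.67. With normexp they were early lymphoid HSC 95.58, early lymphoid CLP/LMPP null 22.45, B lineage HSC 96.31, T lineage HSC 3.86, T lineage LMPP/HSC null 88.11, Notch targets CLP/LMPP null 11.21, natural killer LMPP 88.3, natural killer CLP/LMPP wild type 95.22, mast cell CLP 93.97, hepatocyte CLP/LMPP null 3.78, cell cycle LMPP/HSC null 95.41, MHC class II LMPP 96.65, V(D)J LMPP/HSC wild type 92.55 and oxidative LMPP/HSC null 95.39. Over genes measured on both arrays they were HSC genes CLP 63.78, B lineage HSC 93.57, B lineage CLP/LMPP wild type 80.42, Notch targets CLP/LMPP null 23.81, natural killer LMPP 57.54, natural killer CLP/LMPP wild type 75.08, macrophage LMPP 95.17, dendritic cell CLP/LMPP wild type 86.93, dendritic cell CLP/LMPP null 52.82, mast cell CLP 78.8, endothelial HSC 13.75, interferon HSC 3.92 and V(D)J LMPP/HSC wild type 95.47. Without a detection filter it was interferon HSC 2.53. With the mean over probes they were HSC genes CLP 2.78, early lymphoid HSC 96.03, early lymphoid CLP 95, early lymphoid CLP/LMPP null 31.66, T lineage HSC 7.47, T lineage LMPP/HSC null 94.41, interferon HSC 3.32, V(D)J CLP 85.92 and V(D)J LMPP/HSC wild type 96.9. For correlations, the alternative of genes measured on both arrays uses identical genes and gave no value. A fit of genotype and population with limma, paired by population and added after the data were seen, gave 1 higher gene and 0 lower genes at an adjusted p under 0.05, against 27 and 21 past 2-fold in all 3 populations, and 726 genes at an unadjusted p under 0.05, where 651 are due with no difference. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real split, gave as many genes, the highest other being 0, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05, 3 of the 10 splits, the real one included, gave as many, the highest 1705. Splits that part the arrays of only 1 population, the others of these 3 among them, rest on its genotype labels. They are no check on the real split. The splits that, like the real one, part the arrays of all 3 populations gave 570, 550 and 412 genes, against 726. These are too few for a share under 0.05 as well.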

Other observations

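All of the following was picked after the values were seen. In the limma fit of genotype and population over 6 arrays, none of the genes below had an adjusted p under 0.05: it was 0.664 for Kdm5d and 0.836 for Cdkn1a, Socs3, Klf9, Klhl1, Epha2, Ifit3b, Eif2s3y and Ddx3y.

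Besides the genes named by rule, 3 further genes higher in all 3 populations are given here. Cdkn1a, which encodes a cyclin-dependent kinase inhibitor, was higher by 1.09, 1.25 and 1.33 in HSC, LMPP and CLP by its brightest probe. Its other probe was well above background in LMPP, where it gave -0.22, and not in HSC or CLP. Socs3, a feedback inhibitor of cytokine receptors, was higher by 1.34, 1.65 and at least 1.13, and the transcription factor gene Klf9 by 1.22, at least 1.03 and 1.22. Klhl1 and Epha2 were higher as well, and the interferon-induced Ifit3b was lower.

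Signal of the Y-linked genes Eif2s3y and Ddx3y on the null-labelled arrays was lower than in wild type and not gone. Eif2s3y stood at -2.05, -1.65 and -0.25 on the null-labelled HSC, LMPP and CLP arrays, against 0.38, 0.67 and 0.98 in wild type, and Ddx3y at -1.64, -2.44 and -1.60 against 0.19, 0.44 and -0.63. All of these were well above background. Kdm5d and Uty were not well above background on the null-labelled LMPP and CLP arrays, and stood at -3.13 and -3.78 on the null-labelled HSC array. The source of the Y-linked signal that remained was not tested.

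Arrays of the same population were closer to each other than to those of a neighbouring population. The SD of the difference over 11018 genes was 0.57 between the HSC arrays of the 2 genotypes, 0.48 between the LMPP arrays and 0.76 between the CLP arrays, against 0.59 to 0.66 between HSC and LMPP arrays and 1.0 to 1.15 between LMPP and CLP arrays.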
